A study of Mus musculus with 48 samples.

How the data were processed

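Messenger RNA of the nucleus accumbens shell was measured in 48 mice of an outbred stock, the heterogeneous stock-collaborative cross (HS-CC), after 4 generations of selection for high or low ethanol preference. Per the labels, the shell was taken by laser microdissection, and poly(A)-selected libraries were made with a TruSeq protocol. The labels gave 4 groups of 12 mice: High females, High males, Low females and Low males. The labels gave each library its own sample number and paired no mice. Replicates were numbered 1 to 12 within each group in order of listing, and these numbers serve only as names. Families, litters and cages were not given in the sources used here, and mice were treated as independent.

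The authors deposited a table of genes and a table of exons with 1 column per library. The deposited values are a score: read counts that the authors normalised and then rounded to whole numbers, per the names of the tables and the values themselves, and not raw counts. Per the submitters' processing notes, the tools were CASAVA, FastQC, STAR 2.4.0, R 3.0.2 and edgeR 3.4.2 and the genome build was mm9; no role or order was stated. The counter, the strand setting, the annotation release and the method of normalisation were not given in the sources used here. Reads of a gene and of an overlapping antisense partner could therefore not be told apart. The deposited values covered 37620 genes and 247845 exons; every column was matched to 1 library. The totals of the deposited gene columns ran from 13579559 to 14561911. Regular gaps in the small whole numbers of each column gave an approximate scaling factor per library, and the totals before scaling were estimated from it at 10386310 to 18690667 reads. These are estimates, and whole reads could not be recovered for libraries scaled by a factor below 1, so no count model was fitted. For the same reason no counting interval was attached to single values.

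Symbols, biotypes, chromosomes and transcript sequences came from GENCODE M21 (GRCm38) by Ensembl gene identifier, which matched 32897 genes and left 4723 without a symbol. Positions are those of the deposited exon table on mm9, given as the start of the first listed exon. No position was converted between builds.

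All choices in this paragraph and the next were made before the data were examined. Values were tested with limma 3.58.1 in R 4.3.3 (linear model, contrasts and moderated statistics with a mean-variance trend) on log2(value + pseudocount). Low values were measured in ppm of the mean column total, and for genes 1 ppm was 14.06 deposited units. Genes at 1 ppm or more in at least 12 libraries were kept, which left 15350, and the pseudocount was 0.5 ppm. Fold changes are on this log2(value + pseudocount) scale and understate the change of weakly expressed genes. All 48 libraries entered 1 fit with a mean per group. The contrasts were High minus Low averaged over the sexes, High minus Low in each sex, the difference of these between the sexes, and females minus males averaged over the lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Variability between mice was compared by the same model on absolute deviations from the group median. Exon usage was compared with limma's diffSplice on exons at 0.1 ppm or more in at least 12 libraries, with a pseudocount of 0.05 ppm and a Simes p per gene. Values were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib.

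There were 42 gene lists, 15 of them cell type markers, holding 957 symbols of which 834 matched a tested gene. Lists with 5 or more tested members were compared with limma's camera at a preset correlation of 0.01, with an estimated correlation and limma's fry beside it. Genes were named by a fixed rule. For the line comparison it took called genes with a mean of 5 ppm or more and the same sign in both sexes, the 10 with the largest fold in each direction. For each list it took the called members, up to 4, or at most the 2 members with the smallest p where none was called. For a single sex or the interaction it took 4 genes per direction, for variability 5 per direction, for exon usage 6, and for the sex comparison the called sex-linked list members and up to 5 others per direction.

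The list test used the same mean-variance trend as the gene test; a first run without it had called the same 4 lists. Transcripts of the called genes were compared with all others by shared words of 25 bases, on both strands, to find genes that could exchange reads. Copies elsewhere in the genome were not told apart from genes that overlap at the same place. Among all 1128 pairs of libraries, the closest pair still differed by 8.79 times what counting noise gives, so no library appeared to be deposited more than once. Each test was also run on simulated data with known changes. For the line comparison, 67.2% of simulated log2 changes of 0.3 were recovered, 83.6% of changes of 0.5 and 93.9% of changes of 1, with 7 false calls among 170. For exon usage, 178 of 313 calls on simulated data were false, so that test was poorly calibrated. At a filter of 1 ppm 77 of 168 were false, and with added precision weights 18 of 107.

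Alternatives covered the filter on low values, the pseudocount, quantile normalisation, equal column totals, median-of-ratios rescaling, library weights, blocks of 6 consecutive sample numbers, 2 residual components as covariates, fits within a sex, and other exon and list tests. The leave-out of 1 library, the covariate of pyramidal markers, the weighted exon test, the permutation of mice on list means, the tests of chromosomes and of last exons, and the counts of mice above a level were added after the data were seen. Other splits of the mice were drawn by permuting line labels within sex, and sex labels within line for the sex comparison, 100 for each model with the real one included.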

Results

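Gene expression was compared between mice selected for high and for low ethanol preference (High and Low lines) at selection generation 4, in the shell of the nucleus accumbens, a ventral striatal region of the brain's reward circuit. Each line was represented by 24 mice, 12 females and 12 males, with 1 poly(A) RNA-seq library per mouse. Deposited gene totals ran from 13579559 to 14561911 normalised counts per library, and the number of genes with a value above 0 ran from 19708 to 20888. All 48 libraries matched their sex label by Xist against the Y-linked genes. Libraries correlated closely, with a median of median correlations of 0.976; High male replicate 1 was the lowest at 0.967, just under a limit of 0.969 for a library that stands apart. Each selection direction was 1 population, so p values measure the spread between these mice and cannot separate selection from drift. Family membership was not given in the sources used here.

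The first comparison asked which transcripts differed between the High and Low lines. Rad51d, a gene of homologous recombination, was lower in High, at 225 ± 31.3 (SD, n = 24) against 315 ± 54.8 normalised counts in Low. Rad51c, also of homologous recombination, was higher in High, at 55.2 ± 12.5 against 37 ± 9.82. Fabp5, a fatty acid-binding protein, was 1.37-fold higher in High. Acaca, which encodes acetyl-CoA carboxylase 1 of fatty acid synthesis, had a 1.39-fold higher total in High, none of which was left without its last exon. Sst, the neuropeptide somatostatin of a class of striatal interneurons, was 1.32-fold lower in High, at 1772 ± 388 against 2360 ± 542. In total 43 of 15350 genes differed by limma at an adjusted p under 0.05, 22 higher and 21 lower in High, and all 43 had the same sign in both sexes. Library weights raised the count to 80 and 2 residual components as covariates to 482. The components came from the residuals of the same model and left the log2 differences unchanged. Counts with them, here and below, are therefore no added evidence of a difference.

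Among the named genes higher in High, Acaca had a log2 difference of 0.48 ± 0.081 (SE, adjusted p = 0.00268), with 24 of 24 High mice above the Low median; it was carried by the last exon. Fabp5 rose by 0.46 ± 0.095 (adjusted p = 0.0192). Pcna, the sliding clamp of DNA polymerase, rose by 0.39 ± 0.084 (adjusted p = 0.0233). Ptrh2, a mitochondrial peptidyl-tRNA hydrolase, rose by 0.36 ± 0.068 (adjusted p = 0.00749), and the mismatch repair gene Mlh3 by 0.34 ± 0.075 (adjusted p = 0.0277). Glod4, Peli1 (an E3 ubiquitin ligase) and Cndp2 (a cytosolic dipeptidase) were higher by 1.21-fold, 1.2-fold and 1.18-fold, with adjusted p values of 0.014, 0.0287 and 0.0233. The remaining named members were Gm13339 and Gm13341, nuclear copies of mitochondrial genes, with adjusted p values of 0.0499 and 0.0347. Their mean folds of 14.8 and 12.4 describe no single mouse: in 10 High mice Gm13339 lay between 16035 and 26281 and Gm13341 between 21542 and 31365, and in all other mice between 8 and 165 and between 33 and 254.

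Among the named genes lower in High, Rad51d had a log2 difference of -0.46 ± 0.064 (adjusted p = 4e-05), and 0 of 24 High mice lay above the Low median. Sst had -0.40 ± 0.087 (adjusted p = 0.0233), and 3 of 24 High mice exceeded the Low median. Syndig1l, a striatum-enriched membrane protein, measured 1221 ± 174 in High against 1634 ± 472 in Low (adjusted p = 0.0238). Shpk, the kinase of sedoheptulose, was 1.32-fold lower (adjusted p = 0.0337), and Parvb, the integrin-linked beta-parvin, was 1.26-fold lower (adjusted p = 0.0248). Nudt13 and BC025920 were 1.44-fold and 1.41-fold lower (adjusted p = 0.0347 and 0.0332). The mitochondrial transfer RNAs mt-Ty (tyrosine) and mt-Tw (tryptophan) were 3.89-fold and 1.64-fold lower (adjusted p = 0.0307 and 0.0233). Both were lowest in 10 High mice, the same ones in which the nuclear copy Gm13340 was high: mt-Ty lay between 0 and 12 in these and between 140 and 386 in the 38 other mice, and mt-Tw between 82 and 160 and between 175 and 502. Gm8172, a processed copy of Rps6 on chromosome X, was 8.71-fold lower (adjusted p = 0.011). This fold also describes no single mouse: Gm8172 lay between 371 and 955 in 12 Low mice and between 0 and 4 in all others. Of the 43 called genes, 30 met the rule's conditions on mean and sign, 17 higher and 13 lower in High. The 10 with the largest fold in each direction are those named above. Called genes outside the 30 had lower means.

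**Figure D1:**
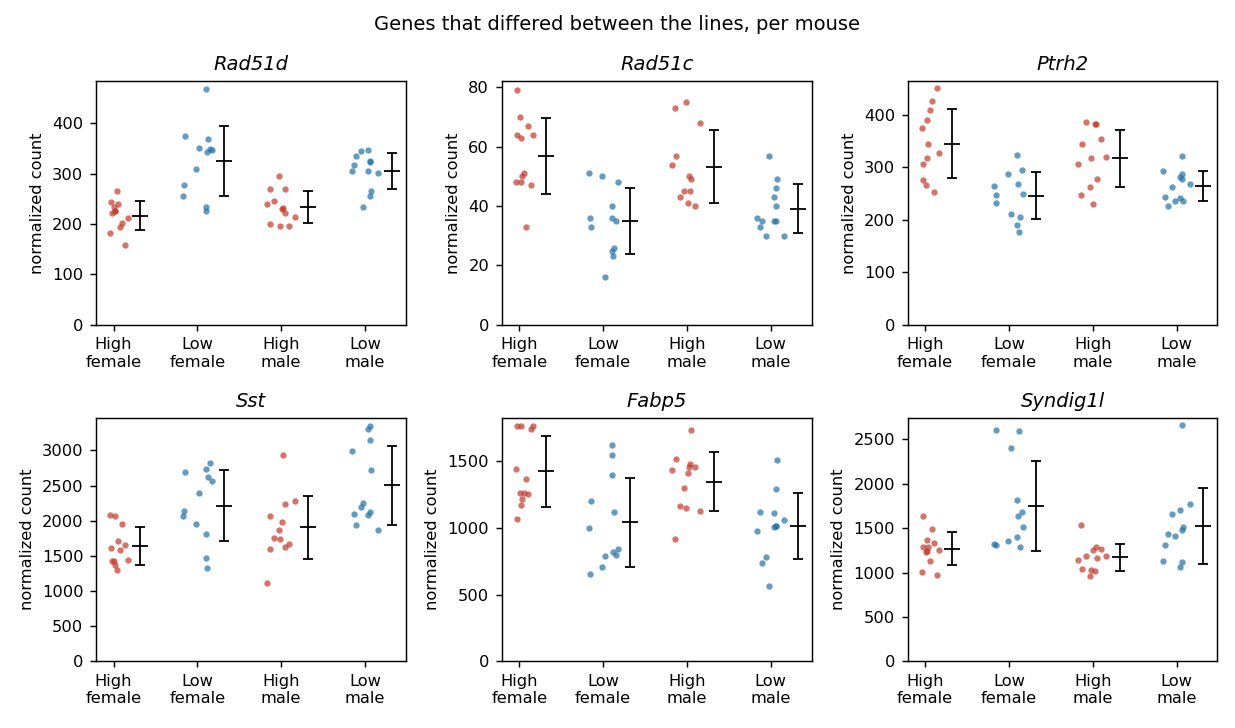
Normalised counts of Rad51d, Rad51c, Ptrh2, Sst, Fabp5 and Syndig1l in each mouse (points) of the 4 groups, with the group mean and SD as a bar beside them. Rad51d is lower in High than in Low in both sexes (225 against 315 over the sexes), and Rad51c and Ptrh2 are higher.

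Called genes were concentrated on chromosome 11, which held 13 of them against 3.48 expected from its 1221 tested genes (Fisher's exact test, two-sided, adjusted p = 0.000461 over 22 chromosomes). The mitochondrial chromosome held 2, mt-Ty and mt-Tw, against 0.0911 expected, but these were lowest in the same 10 mice and are not independent calls. Fisher's test takes the calls on chromosome 11 as independent, while called genes within 20 Mb of each other correlated between mice of the same group. The genes of chromosome 11 were singled out after their values were seen. Of these, higher in High were Peli1, Glod4, Lyrm9, Lgals9, Acaca, Ptrh2, Ska2 and Rad51c, and lower were Rangrf, Shpk, Rilp, Rad51d and Pnmt. Their first exons lay from position 20991294 (Peli1) to 98247764 (Pnmt) on mm9, with Rad51d (ENSMUSG00000018841) at 82685466, Acaca (ENSMUSG00000020532) at 83943174, Ptrh2 (ENSMUSG00000072582) at 86497487 and Rad51c (ENSMUSG00000007646) at 87190147. Pnmt, which makes adrenaline from noradrenaline, was 1.66-fold lower, and Lgals9, the lectin galectin-9, was 1.54-fold higher in High.

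**Figure D2:**
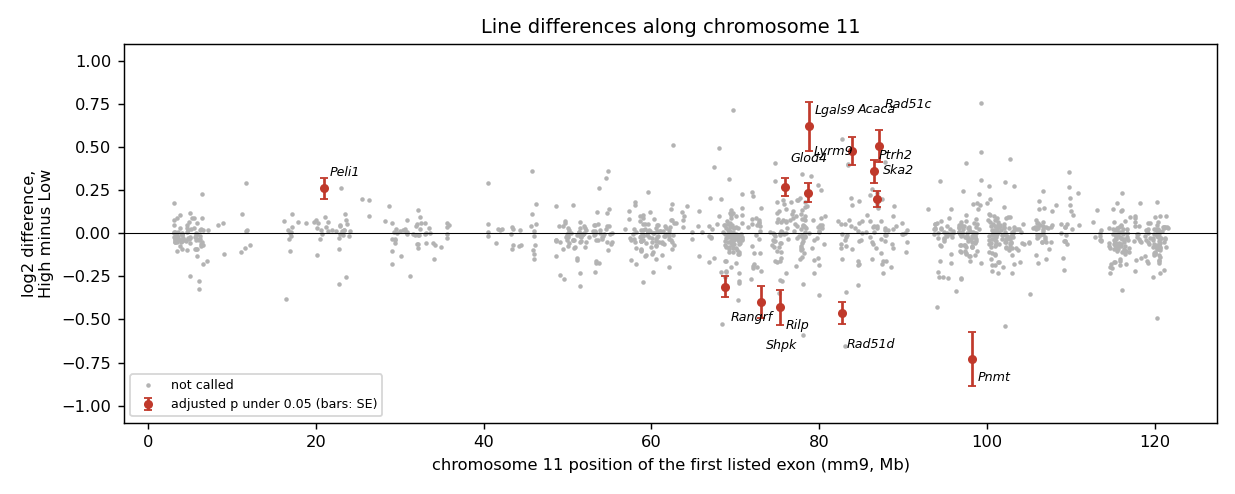
Log2 difference (High minus Low) of each tested gene of chromosome 11 against the mm9 position of its first listed exon in Mb; red points are the 13 called genes with their SE and grey points the others. The called genes have both signs, 8 above 0 and 5 below 0.

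The exon table located some of these differences within genes. For the median of 26 called genes with 4 or more exons, 90.8% of the log2 difference was left without the exon that contributed most. Acaca kept -0.614%: its last exon (starting at 84213062) measured 228 ± 56.3 in High against 139 ± 43.9 in Low, while its other exons together measured 106 ± 41.8 against 99.8 ± 25.4. For Lyrm9 the last exon was higher in High, at 400 ± 54.1 against 319 ± 64.8, and the other exons were lower, at 39 ± 10.8 against 54.6 ± 17.6. The median gene had 55.3% of its value in the last exon, without account of exon length. Pooled over genes within each library, last exons held from 44.9% to 58.4% of the value. The lines differed by 0.341 percentage points in this pooled share (permutation test, two-sided, p = 0.659).

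Several called genes share sequence with another gene, and their values are uncertain where reads could be placed on either. The word search did not separate copies elsewhere in the genome from neighbours that overlap at the same place. Shared words of 25 bases covered 87.2% of Gm8741 (with Snu13), 80.2% of Gm8172 (with Rps6), 80.2% of Pcna-ps2 (with Pcna), 79% of Rangrf (with Slc25a35), 59% of BC025920 (with Gm26896), 54.9% of Glod4 (with Gemin4), 36.3% of Abhd11 (with Gm43372), 32.6% of Acaca (with Gm5182), 31.2% of Ptgr2 (with Gm47484), 25.1% of Pcna (with Pcna-ps2) and 23.3% of mt-Ty (with Cep295). The nuclear copies shared 37.9% (Gm13339 with mt-Nd2), 53.7% (Gm13340 with mt-Co1) and 54% (Gm13341 with mt-Co2) of their words. Of the transcripts called below for variability, mt-Nd4l shared 98.9% with Gm10222 and mt-Nd3 98.1% with Gm28438. Pcna-ps2 was 2.15-fold lower in High while Pcna was higher.

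Cell type marker lists were compared between the lines to describe the tissue itself. Oligodendrocyte and myelin markers lay lower in High, with 14 of 15 members below 0 and a median log2 difference of -0.21; no member passed over all genes by limma, 9 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone. Examples were Opalin at 96.6 ± 33.1 against 126 ± 31.4 and Ugt8a, of myelin galactolipid synthesis, at 145 ± 48.5 against 184 ± 49.1. Indirect-pathway (D2) medium spiny neuron markers lay lower in High for 8 of 9 members (median -0.10), with Upb1 at 264 ± 138 against 374 ± 103 and Gnb4 at 1097 ± 188 against 1190 ± 163; 1 member passed adjusted over the list alone and 0 over all genes, with 1 at an unadjusted p under 0.05. Astrocyte markers lay higher for 11 of 13 members (median 0.07), among them Gjb6 (424 ± 81.3 against 377 ± 56.1) and S100b (1510 ± 676 against 1197 ± 340), with no member called in either way and 1 at an unadjusted p under 0.05. Immediate early genes, which neurons induce on activity, lay higher for 16 of 20 members (median 0.11), including Jun (436 ± 90.7 against 381 ± 62.1) and Nr4a3 (641 ± 227 against 518 ± 228), also with no member called in either way and 1 at an unadjusted p under 0.05.

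The preset camera test called these 4 of 41 lists, with adjusted p values of 2.09e-06 for oligodendrocyte, 0.0314 for D2, 0.0366 for astrocyte and 0.0366 for immediate early genes. None held otherwise: the adjusted p = 0.977, 0.743, 0.977 and 0.977 in that order with an estimated correlation, and fry gave 0.577, 0.384, 0.577 and 0.984. Permutation of the mice on the mean of each list gave adjusted p values of 0.52 for oligodendrocyte and 0.108 for D2 markers. Per mouse, the oligodendrocyte mean differed by -0.19 between the lines against an SD of 0.31 within groups.

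**Figure D3:**
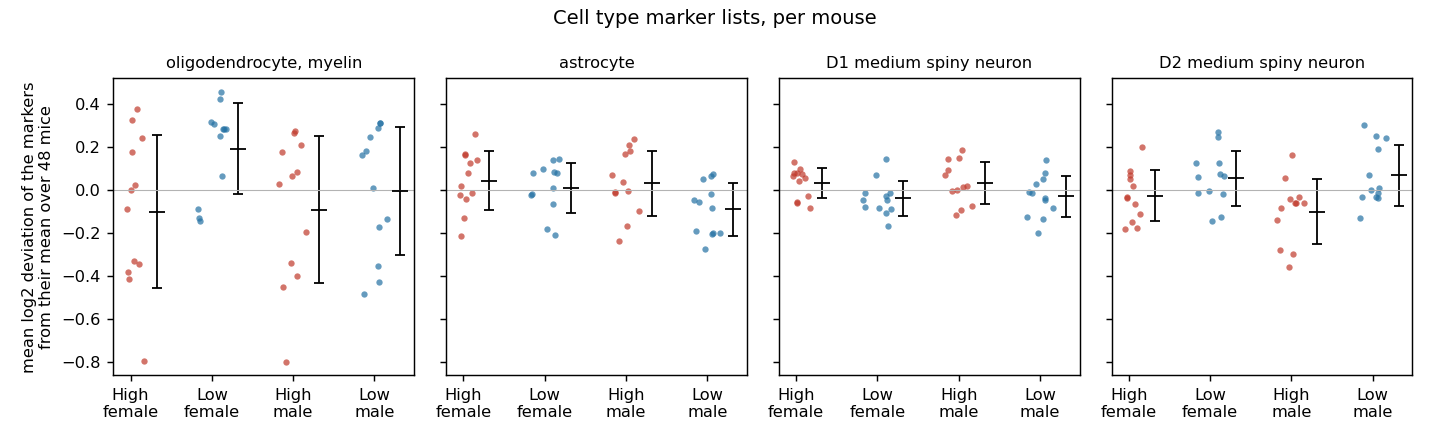
Mean log2 deviation of the markers from their mean over the 48 mice, per mouse (points), with the group mean and SD as a bar, for oligodendrocyte, astrocyte, D1 and D2 medium spiny neuron marker lists in the 4 groups. Among these 4 lists the oligodendrocyte mean varies most between mice, with an SD of 0.308 within groups against a line difference of -0.189.

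Direct-pathway (D1) medium spiny neuron markers lay higher in High for 9 of 10 members (median 0.06, preset adjusted p = 0.0537). None was called, with 2 at an unadjusted p under 0.05, which were Slc35d3 (704 ± 108 against 636 ± 88.2) and Pdyn, the opioid precursor prodynorphin (8544 ± 1332 against 7781 ± 1086). The shared medium spiny neuron list had 0 of 17 members called and 1 at an unadjusted p under 0.05, Rasd2 (4243 ± 709 against 4732 ± 883). Of the shell and ventral striatum list, 0 of 11 members were called and 1 had an unadjusted p under 0.05, Nts, the neuropeptide neurotensin (764 ± 300 against 555 ± 185). The preset adjusted p values of these lists were 0.763 and 0.382.

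Interneuron markers had 1 of 14 members called, Sst, and 3 adjusted over the list alone. For microglia, 1 of 13 members passed adjusted over the list alone, C1qc of the complement system (264 ± 92.2 against 191 ± 53.8), and 1 of 8 ependymal and choroid plexus markers did, Kl (108 ± 23.5 against 84 ± 22.6); neither passed over all genes. No member was called, over all genes or adjusted over the list alone, among 5 pyramidal, 11 septal and diencephalic, 10 oligodendrocyte precursor, 14 endothelial and mural, 10 leptomeningeal and 5 blood markers; those with an unadjusted p under 0.05 numbered 1, 0, 0, 1, 1 and 0. Examples were Rasgrf2 (269 ± 123 against 208 ± 61.8), Acta2 of smooth muscle (290 ± 170 against 204 ± 94.1) and Slc6a13 (54.3 ± 15.4 against 43.5 ± 12.6). Pyramidal markers, of neighbouring cortex, varied strongly between mice: their mean per mouse ran from -0.67 to 2.66 (log2, Low male replicate 6 highest), with an SD of 0.81 within groups against a line difference of -0.11 (permutation p = 0.633). High male replicate 1, the library that stood apart, had 2.04, less than High male replicate 10 (2.20) and Low male replicate 6, which did not stand apart. Preset adjusted p values ran from 0.205 to 0.956 over the lists of this paragraph.

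Receptor and signalling lists gave few differences between the lines. In the opioid, cannabinoid and neuropeptide list 1 of 32 members was called by limma, Sst. In that list 2 members passed adjusted over the list alone and 6 had an unadjusted p under 0.05. Among GABA-A, glycine and GABA-B receptors 0 of 18 members were called over all genes and 3 passed adjusted over the list alone; Gabra3 measured 863 ± 102 against 769 ± 116, and Gabrd, of extrasynaptic receptors, 2149 ± 340 against 2472 ± 430. In the dopamine list 0 of 18 members were called and 3 had an unadjusted p under 0.05, including Ddc, which makes dopamine from L-DOPA (402 ± 92.8 against 329 ± 91.8), and Drd5 (41.2 ± 12.1 against 33.2 ± 12.6). For serotonin, adrenergic, muscarinic and nicotinic receptors 0 of 22 were called and 3 had an unadjusted p under 0.05, Chrna4 among them (119 ± 34.2 against 145 ± 39.4). Neither the 18 ionotropic glutamate receptors nor the 27 metabotropic receptors and scaffolds had a call, with 0 members at an unadjusted p under 0.05 in both. Alcohol and acetaldehyde metabolism had 0 of 12 members called and 3 at an unadjusted p under 0.05, including Aldh1a1 (81.2 ± 19.7 against 65.8 ± 24.9) and Cat, catalase (423 ± 62.9 against 374 ± 70.1). Preset adjusted p values of these 7 lists ran from 0.5 to 0.956.

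Channels and synapses behaved similarly, with no member called among 34 potassium channels, 29 sodium, calcium and HCN channels and 32 synaptic vesicle genes, where 1, 2 and 1 members had an unadjusted p under 0.05. Kcnn2 measured 447 ± 58.5 against 411 ± 67.7, Cacna1i 910 ± 186 against 1039 ± 188, and Rims1, an active zone scaffold, 654 ± 50.1 against 606 ± 58.6. Adhesion and matrix lists had no call among 37 cadherins, 22 clustered protocadherins, 32 extracellular matrix genes and 42 axon guidance genes, with 3, 2, 2 and 2 members at an unadjusted p under 0.05. Celsr1 measured 103 ± 35.7 against 76 ± 33.5, Pcdhb13 93.4 ± 15.7 against 81.6 ± 17.7, Ncan, the proteoglycan neurocan, 2313 ± 215 against 2129 ± 151, and Unc5d 246 ± 68.4 against 206 ± 50.8. None of these 7 lists was called by the preset test, whose adjusted p values ran from 0.405 to 0.956.

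Among the remaining lists, mitochondrially encoded transcripts had 0 of 13 members called over all genes and 5 adjusted over the list alone, among them mt-Nd4l (41 ± 35.9 against 12.6 ± 3.69) and mt-Nd3 (96.2 ± 101 against 20.7 ± 5.34). The circadian list had 0 of 18 members called and 1 adjusted over the list alone, Tef, a PAR bZIP transcription factor (6618 ± 471 against 7133 ± 428). The interferon list had 0 of 17 members called and 1 adjusted over the list alone, Ifitm3 (106 ± 23.5 against 83.9 ± 20.6). Members with an unadjusted p under 0.05 numbered 6, 3 and 3 in these lists. No call was made, over all genes or adjusted over the list alone, in 56 cytosolic ribosomal proteins, where 1 member had an unadjusted p under 0.05 (Rps6, 3489 ± 463 against 3017 ± 659). The value of Rps6 is uncertain, since Gm8172, high in 12 Low mice only, shared 80.2% of its words of 25 bases with it. No call in either way was made for 25 neurotrophin, 30 chromatin, 14 glucocorticoid-responsive, 20 heat shock, 54 nuclear oxidative phosphorylation and 15 histocompatibility genes, each with 0 members at an unadjusted p under 0.05. The escape list of 8 X-linked genes had none called and 0 at that level, and the 4 Y-linked genes, too few for a list test, had none called and 1 (Uty). Preset adjusted p values of the lists in this paragraph ran from 0.205 to 0.956. The median, the mean and the direction of the test differed in sign for the pyramidal, dopamine, serotonin, synaptic vesicle, cadherin, clustered protocadherin, matrix, mitochondrially encoded and escape lists.

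**Figure D4:**
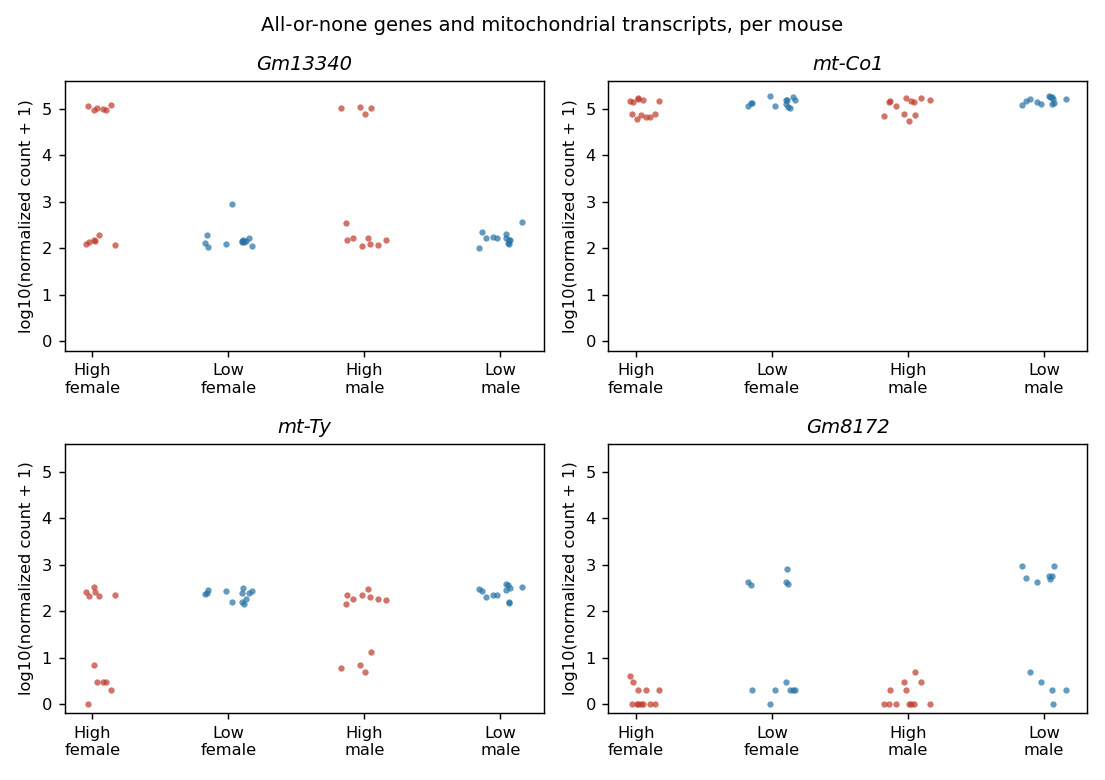
Log10(normalised count + 1) of Gm13340, mt-Co1, mt-Ty and Gm8172 in each mouse of the 4 groups (log axis, points are mice). Gm13340 exceeds 1000 in 10 of 24 High mice and in 0 of 24 Low mice, and Gm8172 exceeds 100 in 12 of 24 Low mice and in 0 of 24 High mice.

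Within each sex the line comparison gave fewer calls. In females Rad51d was lower in High (log2 difference -0.55 ± 0.090, adjusted p = 0.00223), and Acaca (0.65 ± 0.11, adjusted p = 0.00521), Ptrh2 (0.48 ± 0.096, adjusted p = 0.0427) and Rad51c (0.63 ± 0.13, adjusted p = 0.0464) were higher; over both sexes, none of the difference of Acaca was left without its last exon. With 12 mice per group these 4 genes, all on chromosome 11, were the only calls by limma, against 719 genes at an unadjusted p under 0.05. The female count was 1 with the 24 female libraries alone, 2 without a filter, 2 with blocks of 6 sample numbers, 7 with library weights and 19 with 2 residual components. In males the same genes had log2 differences of -0.37 ± 0.090 for Rad51d, 0.30 ± 0.11 for Acaca, 0.25 ± 0.096 for Ptrh2 and 0.38 ± 0.13 for Rad51c. Limma called 0 genes in males, with 1064 at an unadjusted p under 0.05, and 503 with 2 residual components as covariates.

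The difference between the sexes in the line effect was tested directly. No gene passed by limma (0 calls, 368 at an unadjusted p under 0.05, and 32 calls with 2 residual components), so the female calls are not shown to differ from the males: for Rad51d the interaction was -0.18 ± 0.13 and for Acaca 0.35 ± 0.16, both with an adjusted p of 1. The preset list test called 5 lists in females, 5 in males and 8 for the interaction, and 0 of each held with an estimated correlation, where the smallest adjusted p = 0.716, 0.918 and 0.748. In females the oligodendrocyte list had a median of -0.30 (preset adjusted p = 1.45e-11, adjusted p = 0.716 with an estimated correlation) and the interneuron list -0.17 (0.0171, with adjusted p = 0.716). Cytosolic ribosomal proteins had 0.07 (0.000231, with adjusted p = 0.988), heat shock genes 0.05 (0.0378, with adjusted p = 0.988) and histocompatibility genes 0.14 (0.0378, with adjusted p = 0.716). In males the immediate early genes had 0.18 (preset adjusted p = 0.0021), astrocyte markers 0.13 (0.0048), glucocorticoid-responsive genes 0.11 (0.0463), D2 markers -0.10 (0.0463) and mitochondrially encoded transcripts -0.12 (0.0463), each with an adjusted p = 0.918 with an estimated correlation.

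Females and males were compared across both lines as a check of the labels and as the other axis of the design. Xist, the RNA that silences 1 X chromosome, ranged from 9183 to 16658 normalised counts in females and from 9 to 207 in males, and the sum of the Y-linked genes from 2518 to 3851 in males with at most 40 in females. Of the 12 genes called by limma, 7 were higher in females and 5 in males; 2 residual components as covariates raised the count to 213. The 4 tested Y-linked genes, Kdm5d, Eif2s3y, Ddx3y and Uty, were higher in males, with log2 differences (females minus males) from -5.69 for Uty to -7.38 for Eif2s3y and adjusted p values from 6.43e-52 for Kdm5d to 3.71e-41 for Uty. In the list of X-linked genes known to escape inactivation 6 of 8 members were higher in females and 7 passed adjusted over the list alone: Xist (8.63 ± 0.15), Eif2s3x (0.64 ± 0.083), Ddx3x (0.27 ± 0.043) and Kdm6a (0.31 ± 0.053) had the smallest p. Outside these lists Tsix, the antisense partner of Xist, was among the 7 with a higher value in females (2.51 ± 0.18, adjusted p = 8.01e-15); its reads could not be told apart from those of Xist, so the value is uncertain. Brs3, an orphan bombesin-type receptor gene, was higher in males (log2 difference of females minus males -0.62 ± 0.12, adjusted p = 0.00927).

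In the sex comparison the preset list test called 12 of 41 lists, and 1 held with an estimated correlation: the escape list, with an adjusted p = 2.81e-16. Leptomeningeal fibroblast markers had a median log2 difference of 0.22 (preset adjusted p = 2.71e-05, adjusted p = 0.0732 with an estimated correlation), with 0 of 10 members called and 3 adjusted over the list alone. Cytosolic ribosomal proteins had -0.07 (1.53e-07, with adjusted p = 0.702 with an estimated correlation), and immediate early genes 0.13 (0.000397, with adjusted p = 0.652 with an estimated correlation).

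Variability between mice was compared because lines can differ in spread as well as in level. By limma 9 genes were called, of which 8 varied more in High and 1 more in Low, against 609 genes at an unadjusted p under 0.05. All 8 were mitochondrial transcripts or genes that share sequence with them, and they are not taken as 8 independent findings: beside the 5 below these were mt-Nd4l, mt-Ty and mt-Tc. The 5 with the smallest p in High were Gm13339, Gm13340, Gm13341, Gm11407 and mt-Nd3, with mean absolute log2 deviations of 4.24, 4.18, 3.77, 3.13 and 1.36 against 0.45, 0.35, 0.34, 0.52 and 0.15 in Low (adjusted p values from 1.38e-08 to 0.000241). The first 3 are nuclear copies of mitochondrial genes, and Gm11407 shared 17.9% of its 25-base words with mt-Nd5. At a filter of 5 ppm of the mean library total 5 genes were called. Gm8172 varied more in Low, by 2.68 against 0.14 (adjusted p = 0.0019). These genes were nearly all-or-none: Gm13340 lay between 76224 and 118994 in 10 High mice (6 females, 4 males) and between 102 and 901 in all others, and Gm8172 lay between 371 and 955 in 12 Low mice (5 females, 7 males) and between 0 and 4 in all others. By Fisher's exact test (two-sided) the lines differed with p = 0.0006 and p = 7.76e-05, for levels chosen after the values were seen and on the assumption that the mice are unrelated.

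Exon usage, the share of an exon within its gene, was compared last. An exon of Tra2b, a splicing regulator, at chromosome 16 position 22252680 was used less in High (log2 usage difference -2.16 ± 0.23, adjusted p = 2.25e-14). It measured 24.3 ± 25.7 against 40.1 ± 18.3 normalised counts, and 17 of 24 High mice lay below the Low median of usage. The log2 difference exceeds what these exon means alone would give. It does not describe every High mouse: the SD in High exceeded the mean, and 7 of 24 lay above that median. An exon of Tubg2, a gamma-tubulin gene, at chromosome 11 position 101022108 was used more in High (1.27 ± 0.17, adjusted p = 1.03e-08), with 44.2 ± 25.3 against 21 ± 15.8. Washc3 (0.95 ± 0.13), Zmynd8 (1.30 ± 0.19) and Supt4a (1.16 ± 0.18) each had an exon used more in High, and Dap3 (-0.67 ± 0.10) 1 used less, all at means below 5 normalised counts. In all 75 of 14702 genes passed (782 at an unadjusted Simes p under 0.05), 21 with the extreme exon used more and 54 used less in High, and 0 of the 75 were among the 43 line genes.

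The planned exon test called false positives on simulated data, and the count fell to 20 at a filter of 1 ppm, to 20 with an F test, to 32 with a pseudocount of 0.5 ppm and to 15 with precision weights at 1 ppm. Tra2b and Tubg2 were among 9 genes called with and without weights at 1 ppm; the others included Alkbh3, Lyrm9, Cox7a2l, 1110038F14Rik, Zfand1 and Psmb3. Cox7a2l, a factor of respiratory chain supercomplexes, had an exon at 60 ± 46.8 in High against 121 ± 44.8 in Low.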

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

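The list tests of the difference between the sexes were planned; the tests of myelin variation between dissections, with the cortex markers as a covariate, were chosen after the result was seen. The preset camera test of the interaction called 8 lists, none of which was called with an estimated correlation, where the adjusted p was 0.748 or 0.766 for each. Of 100 splits of the mice within sex, 47 called as many lists, the real one included, and the highest other split called 16, so chance was not excluded. In the preset test, cytosolic ribosomal proteins had a median log2 difference (High minus Low) of 0.07 in females and -0.04 in males (adjusted p = 1.35e-06). Oligodendrocyte and myelin markers had -0.30 and -0.08 (adjusted p = 0.000659), and mitochondrially encoded transcripts 0.01 and -0.12 (adjusted p = 0.00659). Glucocorticoid-responsive genes had -0.01 and 0.11 (adjusted p = 0.00667), immediate early genes 0.02 and 0.18 (adjusted p = 0.00904), and serotonin, adrenergic, muscarinic and nicotinic receptors -0.04 and 0.07 (adjusted p = 0.00904). Potassium channels had -0.01 and 0.04 (adjusted p = 0.0386) and astrocyte markers 0.02 and 0.13 (adjusted p = 0.0426).

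The lower level of oligodendrocyte and myelin markers in High was weighed because 14 of 15 members lay on 1 side. For the line effect, 78 of 100 splits called as many lists as the real 4, with 17 in the highest other, so chance was not excluded for the list calls. A candidate explanation is myelin content that varies between dissections, since the first component held 72.5% of the variance of the markers between mice of the same group. The permutation p of the line difference was 0.0393, under the bound of 0.05 set against this explanation, but that bound was wrong: it took no account of 41 lists (adjusted p = 0.52), and dissections could also have differed by line; it was set aside after the value was seen. Markers of neighbouring cortex, another sign of the dissection, ran from -0.67 to 2.66 per mouse and as a covariate left the difference at -0.183 ± 0.0891 (SE) from -0.189 ± 0.0888, but white matter had no marker here apart from myelin itself, so a difference in myelin between the lines and a difference between dissections cannot be told apart.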

How the results depend on the processing

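The leave-out of High male replicate 1, the covariate of pyramidal markers, the precision weights for exons and the split of the exon test at 1 ppm were chosen after the data were seen; the other alternatives were planned. Of 82 alternatives 65 gave a count within 1.5 times the reported one and 17 did not, and no count of genes that was above 0 fell to 0. The 65 included 12 for males and 11 for the interaction, where the reported count was 0. The others were 10 of 12 for the line effect, 8 of 13 in females and 11 of 12 for sex. For variability they were 6 of 7, for exon usage 3 of 7 and for lists 4 of 6. For the line effect, 40 of the 43 genes were also called with library weights (80 genes). All 43 were also called with 2 residual components as covariates (482 genes). That was close to fixed in advance, since these covariates left the log2 differences unchanged. The components raised the counts also in females (19), in males (503), for the interaction (32) and for sex (213); of 100 splits, 18 called as many line genes as 482 under these covariates and the highest other called 3169, so a raised count also arose without a line difference. The components were taken from the residuals of the same model. They left the log2 differences unchanged and reduced only the residual spread, so a higher count under them is no added evidence of a difference. Chance was not excluded for the 482 genes, and no splits were run with the components for the other counts. The female count of 4 moved to 2 without a filter, to 2 with blocks of 6 sample numbers, to 7 with library weights and to 1 with the 24 female libraries alone, where fewer libraries entered. The variability count of 9 moved to 5 at a filter of 5 ppm, with 5 shared, which tested fewer genes. The exon usage count of 75 moved to 20 with an F test, 20 at 1 ppm, 32 with a pseudocount of 0.5 ppm and 15 at 1 ppm with precision weights; 19, 13, 16 and 7 of these were among the 75. The 4 called lists became 0 with an estimated correlation and 0 with fry. The cause was not tested for the other changes.

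Without High male replicate 1 the counts were 47 for the line effect (41 shared), 4 in females, 0 in males (854 at an unadjusted p under 0.05 by limma), 0 for the interaction (294), 12 for sex, 9 for variability, 93 for exon usage and 4 for lists, of which 3 were shared. With the mean of the pyramidal markers as a covariate they were 42 (40 shared), 4, 0, 0, 12, 8, 75 (71 shared) and 3 (3 shared), in the same order. Blocks of 6 sample numbers and median-of-ratios rescaling left the same 4 lists called. The 10 count-model fits listed before the data were examined were not run, since the deposited values are not raw counts and whole reads could not be recovered for libraries with a scaling factor below 1. Depth before scaling was estimated at 10386310 to 18690667 reads. In the exon test, simulated changes of 1 (log2) were recovered in 56.6% of exons with a mean under 50 and in 96.4% of the others. No paired analysis was possible because the labels pair no mice, and the replicate numbers 1 to 12 of each group are only names. Blocks of 6 consecutive sample numbers are not pairs.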

Other observations

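The tests of called genes within 5 Mb, of the mitochondrial copies and of the balance of D1 and D2 markers were chosen after the results were seen; the splits of the mice, the neighbour test, the residual correlation and the exon test were planned before their results. Alone, neither the D1 nor the D2 list passed with an estimated correlation (adjusted p = 0.743 for both) or by permutation of the mice (adjusted p = 0.249 and 0.108). The mean of 10 D1 markers minus the mean of 9 D2 markers was higher in High by 0.19 (log2), by 0.15 in females and 0.23 in males, against an SD of 0.16 within groups, and 20 of 24 High mice lay above the Low median. Among D1 markers Drd1, the D1 dopamine receptor, measured 2654 ± 329 in High against 2552 ± 306 in Low (SD, n = 24), and Tac1, the substance P precursor, 14161 ± 1643 against 13680 ± 1940. Among D2 markers Drd2 measured 3437 ± 508 against 3732 ± 583 and Adora2a, an adenosine receptor gene, 5575 ± 874 against 5903 ± 971. None of these genes was called alone, and 2 of 10 D1 and 1 of 9 D2 markers had an unadjusted p under 0.05 by limma. How far the balance rests on single markers was not tested.

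A hypothesis is that the lines may differ in the relative expression of D1 and D2 marker genes. Permuting the mice within sex gave a two-sided p of 0.00016 for this balance. Of all 820 pairs of lists the D1 and D2 pair ranked 1, and its p over all pairs was 0.0345, which takes account of the choice of the pair. The levels of markers do not give numbers of cells, and relatedness of mice within a line was not used here.

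The interneuron markers that lay lowest in High beside Sst were Npy, neuropeptide Y, at 1154 ± 258 against 1392 ± 258 and Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, at 225 ± 30.4 against 249 ± 31.6. Pvalb, of another interneuron class, measured 76.9 ± 47.2 against 57.2 ± 35.7. These 3 were not called over all genes.

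The 43 line genes were weighed against chance, linked haplotypes and strain variants under single exons. Of 100 splits 1 called as many genes, the real split itself, and the highest other called 0; splits treat mice as unrelated, so this excludes chance among unrelated mice and not the founder effects of 1 family. Linked haplotypes at different frequency in the lines are a candidate explanation: 28 called pairs lay within 5 Mb, against a 95th percentile of 8 (permutation p = 1e-04), and called genes within 20 Mb correlated between mice of the same group (median absolute residual correlation 0.246 against 0.126 for shuffled positions, p = 1e-04), both p values being the smallest that 10000 permutations can give. These 2 tests used the 38 called genes with a position, mitochondrial genes and their nuclear copies left out. Directly neighbouring called pairs numbered 1 (p = 0.11), within the range set in advance against linkage, but that bound was wrong, since haplotypes span many Mb and 1 pair already equals the 95th percentile; it was set aside after the value was seen. A variant that loses reads in 1 exon is argued against only for the median of the 26 called genes with 4 or more exons. That median kept 90.8% of the difference without the strongest exon. Of these genes 2, Acaca and Lyrm9, kept under 50% and stay open. Variants spread over several exons of a gene were not tested, nor were called genes with fewer exons, so reads lost at such variants stay open. Selection and drift were not separated.

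The high values of Gm13339, Gm13340 and Gm13341 in 10 High mice were weighed against reads placed on nuclear copies and against more mitochondrial RNA. Within High, adding Gm13340 to mt-Co1 reduced the SD between mice to 0.318 of that of mt-Co1 alone, and adding Gm13339 to mt-Nd2 reduced it to 0.367 of that of mt-Nd2, as reads exchanged between mitochondrial genes and copies would. More mitochondrial RNA in High as a line is argued against, since the sum of mt-Nd1, mt-Cytb and mt-Nd4 differed by 0.04 (log2) with an upper 95% bound of 0.179. This sum was not compared between the 10 mice and the other High mice. Of its members, mt-Cytb ran from 87623 to 150571 in the 10 and from 100620 to 162491 in the other High mice. A mitochondrial haplotype of some founders that matches the nuclear copy better than the reference may therefore be present in some High families, which was not tested against sequence here. The mitochondrial transcripts called for level or spread, such as mt-Ty and mt-Nd3, may share this source and stay uncertain.

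Other splits of the mice were run for each further count. In females 1 of 100 splits called as many genes, the real one, with 4 against 1 in the highest other. This excludes chance among unrelated mice and not the founder effects of 1 family, and all 4 genes lie on chromosome 11. With the 24 female libraries alone the count was 1, and no splits were run for that fit. In males and for the interaction, where 0 genes were called, the splits decide nothing, since any split (100 of 100) calls at least 0; the highest other called 1 and 3. For sex the real 12 stood against 4 (1 of 100), so chance was excluded for the count as a whole. That outcome was close to fixed in advance, since 4 Y-linked genes and 6 genes of the escape list were among the 12. It decides nothing for a single call such as Brs3. For variability 9 stood against 0 (1 of 100), which excludes chance among unrelated mice and not the founder effects of 1 family. Of the 9 genes, 8 were mitochondrial transcripts or genes that share sequence with them and are not independent. For exon usage 4 of 100 splits called as many as 75, with 112 in the highest other and a median of 32; at 1 ppm 2 of 100 called as many as 20, with 30 in the highest other and a median of 2. These shares lie under 0.05, but narrowly: 3 other splits reached the real count at all exons and 1 did at 1 ppm, so chance was excluded for no single exon call, and the exon counts remain uncertain.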
